A study of Macaca nemestrina with 10 samples.

How the data were processed

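Gene expression was measured in myometrium, the muscle layer of the uterine wall, taken from the lower uterus of pregnant pig-tailed macaques, with 1 array per animal. Per the labels, 5 animals were saline controls without labor, 3 had an inflated intra-amniotic balloon and went into labor, and 2 had the balloon without labor. The RNA was hybridised to the Affymetrix Rhesus Macaque array, whose probes were designed on a related species, so sequence differences between the species can lower the signal of a probe set.

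The deposited table holds log2 expression values per probe set. The submitters' processing notes name RMA, which corrects background, normalizes quantiles and summarises probes, and the R package oligo. Their versions and any genome build are not given in the sources used here. The values run from 1.73 to 14.47 with 0 missing, and array medians lie between 4.81 and 4.87. The scanner files were not used here, so background could not be corrected again. The number of arrays limits the precision of each value.

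Of 52865 probe sets, 158 control probe sets were left out of the tests. Names came from the platform annotation of the array: 24956 of the other 52707 probe sets have exactly 1 gene symbol, 361 have several and 27390 are unnamed here. Each gene was represented by the probe set with the highest mean over the 10 arrays among those with 1 symbol, which gave 14132 genes; 6375 of them have more than 1 probe set and 1139 have a locus symbol without a gene name. A gene table of the species' own assembly shared no gene identifiers with this annotation and was not used. No coordinates are given.

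Genes were tested with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Stretch was compared with control in a model of 2 groups. Stretch with labor and stretch without labor were each compared with control, and with each other, in a model of 3 groups that shares 1 estimate of the spread. Gene lists were tested with camera from limma, which compares a list with all other genes, with a preset inter-gene correlation of 0.01 and adjustment over 37 lists (18 pathway lists and 19 lists of cell type markers) with at least 5 measured members. The mean of each list per array was also compared with a two-sided exact permutation test. The level of a list on an array is the mean log2 value of its members minus the mean over controls.

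The comparisons, lists, tests and most alternatives were set before the data were examined. Named genes follow a rule set then: genes past the threshold, and where fewer than 10 pass in a direction in stretch against control, the 10 of smallest unadjusted p; up to 4 members of smallest p in each list described; and a panel of 11 genes of inflammation and labor, of which 8 had a probe set with 1 symbol and the others were not analysed here. The lists described although they did not pass were chosen after their values were seen, as were the genes EPHB1, VCAM1, RASD1 and SOX4 in the labor comparisons.

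The tests were checked on data simulated from the real means and residual spread of the 14132 genes, with 100 genes changed 2-fold and 100 changed 4-fold. limma recovered 89% and 95% of them for stretch against control, 82% and 94% for stretch with labor against control, 68% and 95% for stretch without labor against control, and 70% and 93% between the stretch groups. Of the unchanged genes it called 3, 8, 11 and 4. These genes were simulated as independent, and real genes vary together. The residual spread came from the model of 3 groups, and no labor difference was simulated. In the real data the model of 2 groups holds labor differences in its spread. Recovery for stretch against control may therefore be lower than simulated, as it may be where fewer genes change. With 2 lists shifted by 0.30 log2, camera called both and 0 of the other 35 in each comparison. Genes were independent in this simulation too, so it does not show how often camera calls unchanged lists whose genes vary together. In stretch against control the estimated correlation was 0.24 for oxidative phosphorylation, 0.43 for type I interferon and 0.19 for antigen presentation, above the preset 0.01. For cell proliferation it was 0.73 in stretch with labor against control and against stretch without labor. Its members therefore moved largely together.

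Alternatives were another prior (trend and robust), array weights, another quantile normalization, centring on array medians, all probe sets, the mean of a gene's probe sets, a filter at the median level, looser thresholds, the other group model, leaving out each array in turn, the replicate number as a block and an estimated inter-gene correlation. Added after seeing the data were leaving out stretch with labor replicate 3 and control replicate 1, the arrays that stood furthest apart on the first and second principal component, the difference between 3' and 5' control probe sets as a covariate, and the exact test of list means.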

Results

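Myometrium of the lower uterus was profiled in 10 pregnant pig-tailed macaques (Macaca nemestrina), catheterized animals at 118 to 125 days of a gestation whose term is 172 days. In 5 animals a balloon inside the amniotic sac was inflated to stretch the uterus, and 5 controls received saline. Of the stretched animals, 3 went into labor and 2 did not. The design asks how stretch changes the expression of the uterine muscle, and whether stretched animals in labor differ from those that were not. Values are log2 expression per gene, and errors are SD between animals unless stated.

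The arrays correlated with each other at 0.973 to 0.991. The first principal component held 28.8% of the variance and set stretch with labor replicate 3 (44.8) and replicate 2 (17.6) apart from the other arrays, which lay between -18.0 and 4.73. The second held 19.2% and set control replicate 1 (38.9) apart. The difference between 3' and 5' control probe sets, a sign of RNA degradation, averaged 1.38 ± 0.12 log2 in stretch (n = 5) and 1.54 ± 0.17 in control (n = 5; exact two-sided permutation p = 0.0873).

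**Figure D1:**
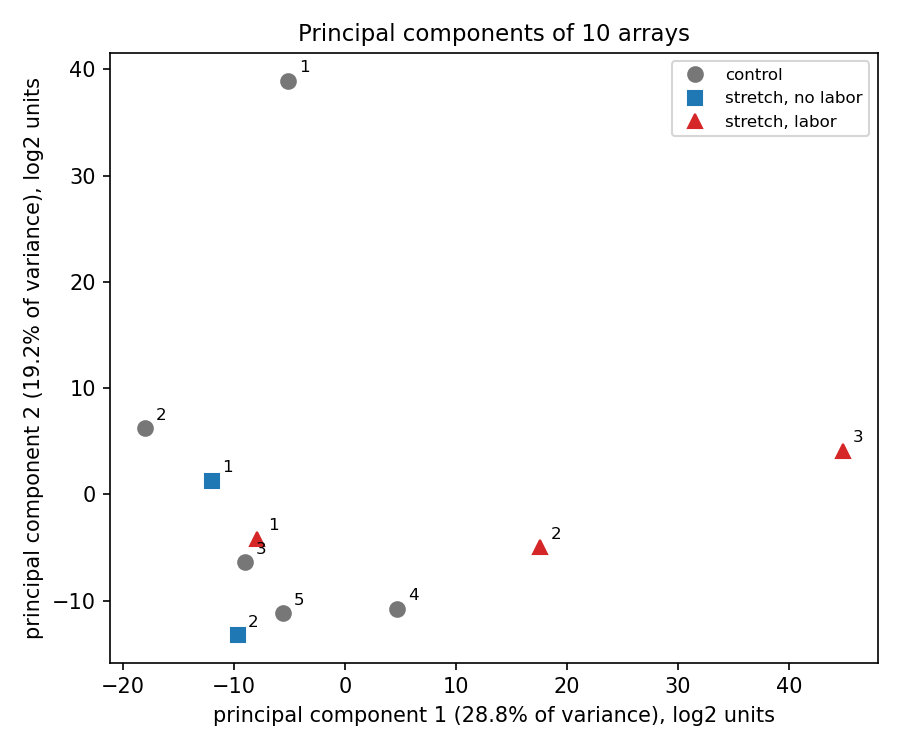
Principal components 1 and 2 of the log2 expression of 14132 genes on 10 arrays, with the share of variance on each axis; each point is an animal, numbered by replicate within its group. Stretch with labor replicate 3 lies at 44.8 on the first component and control replicate 1 at 38.9 on the second.

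Stretch against control addressed the effect of balloon inflation whatever its outcome. Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, were higher in stretched animals: 20 of 23 measured members lay higher, by a mean of 0.15 log2, and the list level was 0.15 ± 0.08 in stretch and 0.00 ± 0.07 in control (n = 5 each). Genes of the type I interferon response, the antiviral programme, were higher in 19 of 22 members, by a list mean of 0.48 log2 (0.32 to 0.63 with 1 array left out). Genes of antigen presentation were higher by 0.17 log2 in 12 of 14. camera called these 3 of 37 lists, with Benjamini-Hochberg adjusted p = 3.52e-08, 9.01e-08 and 0.0126. None of the calls held when the correlation between genes was estimated (camera adjusted p = 0.699 for each with an estimated correlation), and the exact permutation test of the list levels gave p = 0.0238, 0.0635 and 0.222 before adjustment and at least 0.44 after it. Of 100 splits of the 10 arrays into 2 groups of 5, 80 gave 3 or more called lists, and 94.9% of the splits other than the real one called at least 1.

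Within the interferon list, 5 members passed when adjusted over the list alone and 0 over all genes. ISG15, a ubiquitin-like protein induced by interferon, measured 7.96 ± 0.79 in stretch and 6.79 ± 0.29 in control (difference 1.17, SE 0.33). OAS2 differed by 0.89 (SE 0.26), RIGI, a sensor of viral RNA, by 0.78 (SE 0.23) and IFIT1 by 0.95 (SE 0.30). The list level differed widely between animals: it was 1.14 in stretch without labor replicate 2 and -0.11 in stretch with labor replicate 3. In the oxidative phosphorylation list, SDHB of complex II differed by 0.29 (SE 0.08), NDUFA2 of complex I by 0.36 (SE 0.11), the ATP synthase subunit ATP5F1B by 0.33 (SE 0.10) and UQCRC2 of complex III by 0.25 (SE 0.09). In the antigen presentation list the immunoproteasome subunits PSMB10 and PSMB8 differed by 0.42 (SE 0.13) and 0.35 (SE 0.12), the peptide transporter TAP1 by 0.24 (SE 0.09) and the protease CTSS by 0.40 (SE 0.21). Among other settings, that list lost its call without stretch with labor replicate 1 (mean 0.099, camera adjusted p = 0.145) and without control replicate 4 (mean 0.098, camera adjusted p = 0.0532). With the mean of each gene's probe sets the call was lost too (mean 0.11, camera adjusted p = 0.117). With 1 array left out the list's mean ran from 0.098 to 0.25. Its camera adjusted p ran from 1.41e-06 to 0.699 over its 17 alternatives.

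**Figure D2:**
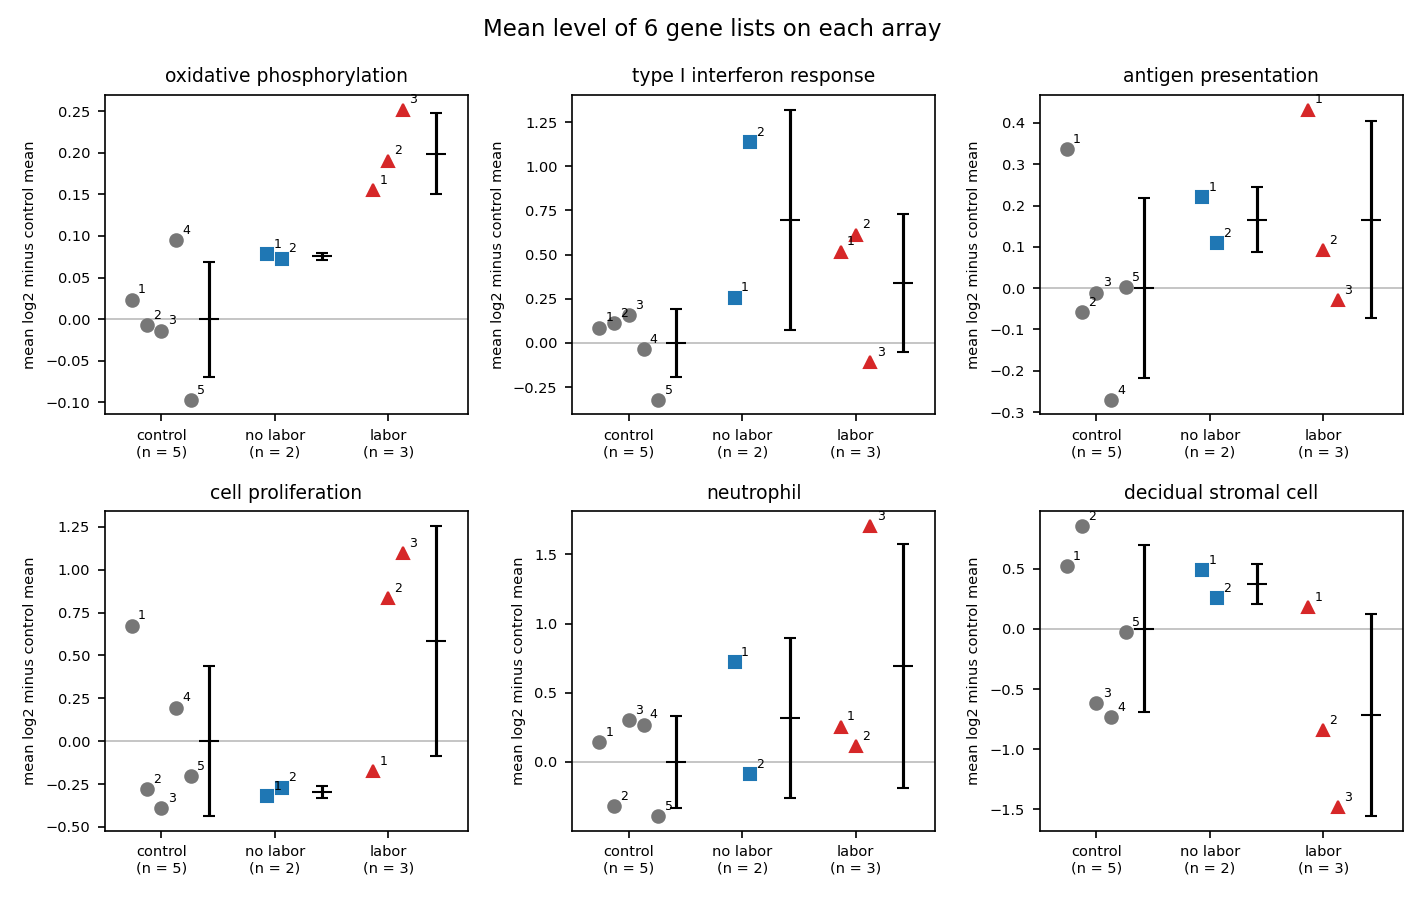
Mean log2 level of 6 gene lists on each array, relative to the control mean, in controls, stretch without labor and stretch with labor; points are animals numbered by replicate, and bars beside them give the mean and SD. Oxidative phosphorylation lay between 0.07 and 0.25 in stretch and reached 0.095 in control replicate 4, above the stretch arrays without labor. Proliferation stood at 0.83 and 1.10 in 2 of the 3 labor arrays and at 0.67 in control replicate 1.

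No single gene passed: limma called 0 of 14132 genes (smallest adjusted p = 0.783), with 892 at an unadjusted p under 0.05 where chance gives 706.6. Of those 892, 448 were higher and 444 lower (50.2% higher); with arrays centred on their medians, 65.2% were higher. Genes whose stretch and control values did not overlap numbered 177 (1.25%), and chance gives 0.794%. The 10 higher genes of smallest unadjusted p, none of which passed, were CRYAB, GCH1, SLC25A51, DGKH, KGD4, DYNLT2B, OPA1, DDA1, TFDP1 and EPSTI1. CRYAB, a small heat shock protein of muscle, measured 10.27 ± 0.12 in stretch and 9.34 ± 0.39 in control, with a 95% interval of the difference from 0.56 to 1.29. Its second probe set lay lower in stretch by -0.29. GCH1, the first enzyme of tetrahydrobiopterin synthesis, differed by 0.75 (SE 0.14), and OPA1, which fuses inner mitochondrial membranes, by 0.29 (SE 0.06). The corresponding lower genes were TMEM171, CRYL1, IGFBP4, RNF167, DDX60, PTK7, POLL, EXOC2, DNAI4 and SUSD4. IGFBP4, which binds insulin-like growth factors, measured 10.23 ± 0.19 in stretch and 10.95 ± 0.29 in control (difference -0.72, SE 0.14). DDX60 differed by -0.36 and by 0.079 with the mean of its probe sets.

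Among lists that did not pass, genes responsive to YAP and mechanical stretch were higher in 15 of 26 members (mean 0.16, median 0.049, camera adjusted p = 0.0501), with 2 members past the threshold when adjusted over the list alone. CCN2, a matrix protein induced by mechanical load, measured 12.05 ± 0.43 in stretch and 11.20 ± 0.20 in control (difference 0.84, SE 0.19, limma adjusted p = 0.783), and all 5 stretch values lay above all 5 control values; 1 of its 3 probe sets went in that direction. The integrin ITGB1 differed by 0.40 (SE 0.10), the growth factor HBEGF by 0.94 (SE 0.33; -0.074 in its other probe set) and GADD45B by 0.57 (SE 0.22). Neutrophil markers were higher in 7 of 9 members (mean 0.54, median 0.20, camera adjusted p = 0.0501), a value set mainly by stretch with labor replicate 3, whose list level was 1.71. The calprotectin subunits S100A9 and S100A8 differed by 2.07 (SE 0.97) and 1.76 (SE 0.98), MMP8 by 0.20 (SE 0.14) and CSF3R by 0.18 (SE 0.14). Without that array S100A9 differed by 1.26, S100A8 by 0.89, MMP8 by 0.061 and the chemokine CCL2 by 0.76. Markers of glandular or squamous epithelium were lower in 8 of 10 members (mean -0.33, camera adjusted p = 0.0501), with KRT18 at -0.56 (SE 0.23), MUC1 at -0.25 (SE 0.10), CLDN4 at -0.25 (SE 0.12) and KRT8 at 0.18 (SE 0.11).

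Lists of inflammation and contraction did not pass. Cytokines and chemokines had 16 of 25 members higher (mean 0.12, camera adjusted p = 0.685); CCL2, a chemokine that draws monocytes, differed by 1.43 (SE 0.77), IL10 by 0.40 (SE 0.19), CSF3 by -0.11 (SE 0.07) and TNF by -0.25 (SE 0.14). NF-kappaB and Toll-like receptor signalling had 20 of 29 members higher (mean 0.060, camera adjusted p = 0.218), with the endothelial adhesion molecules SELP at 0.51 (SE 0.17) and VCAM1 at -0.81 (SE 0.30), SOD2 at 0.22 (SE 0.10) and TNFAIP2 at -0.38 (SE 0.17). Genes associated with labor contraction had 6 of 13 measured members higher (mean 0.0022, median -0.026, camera direction higher, adjusted p = 0.899). The list names 22 genes. PTGS2, GJA1 and PTGFR had no probe set with exactly 1 gene symbol and were not tested. PTGS2 is also absent from the prostaglandin genes tested below. The oxytocin receptor OXTR differed by -0.12 (95% interval -0.96 to 0.73), the progesterone receptor PGR by -0.11 (-0.65 to 0.43), the estrogen receptor ESR1 by 0.11 (SE 0.12), PTGER1 by -0.10 (SE 0.06), NOS3 by 0.13 (SE 0.09) and KCNMA1 by 0.17 (SE 0.18). Of the smooth muscle contractile genes 7 of 19 were higher (mean -0.033, while camera placed the list above other genes, adjusted p = 0.899), with CNN1 at 0.25 (SE 0.10), ITGA8 at -1.12 (SE 0.58), PPP1R14A at 0.31 (SE 0.17) and TAGLN at 0.14 (SE 0.09). Prostaglandin genes had 6 of 11 higher (mean -0.028, median 0.0079, camera direction higher, adjusted p = 0.899), among them the prostacyclin synthase PTGIS at 0.39 (SE 0.15), PLA2G5 at -0.12 (SE 0.08), PTGES3 at -0.28 (SE 0.24) and TBXAS1 at 0.09 (SE 0.12). IL1B differed by 0.062, IL6 by 0.32 (SE 0.44) and CXCL8 by 0.086. The levels of several panel genes were low among all genes, at percentile 9.5 for ESR1, 14.6 for CXCL8, 19.4 for TNF, 30.2 for IL1B and 35.4 for IL6. OXTR, CCL2 and PGR stood at 54.7, 61.9 and 73.7. In each comparison, small differences of the low genes therefore do not show that they were unchanged. limma called 0 of the 8 panel genes over all genes and 0 when adjusted over those 8 genes alone (smallest adjusted p = 0.42).

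**Figure D3:**
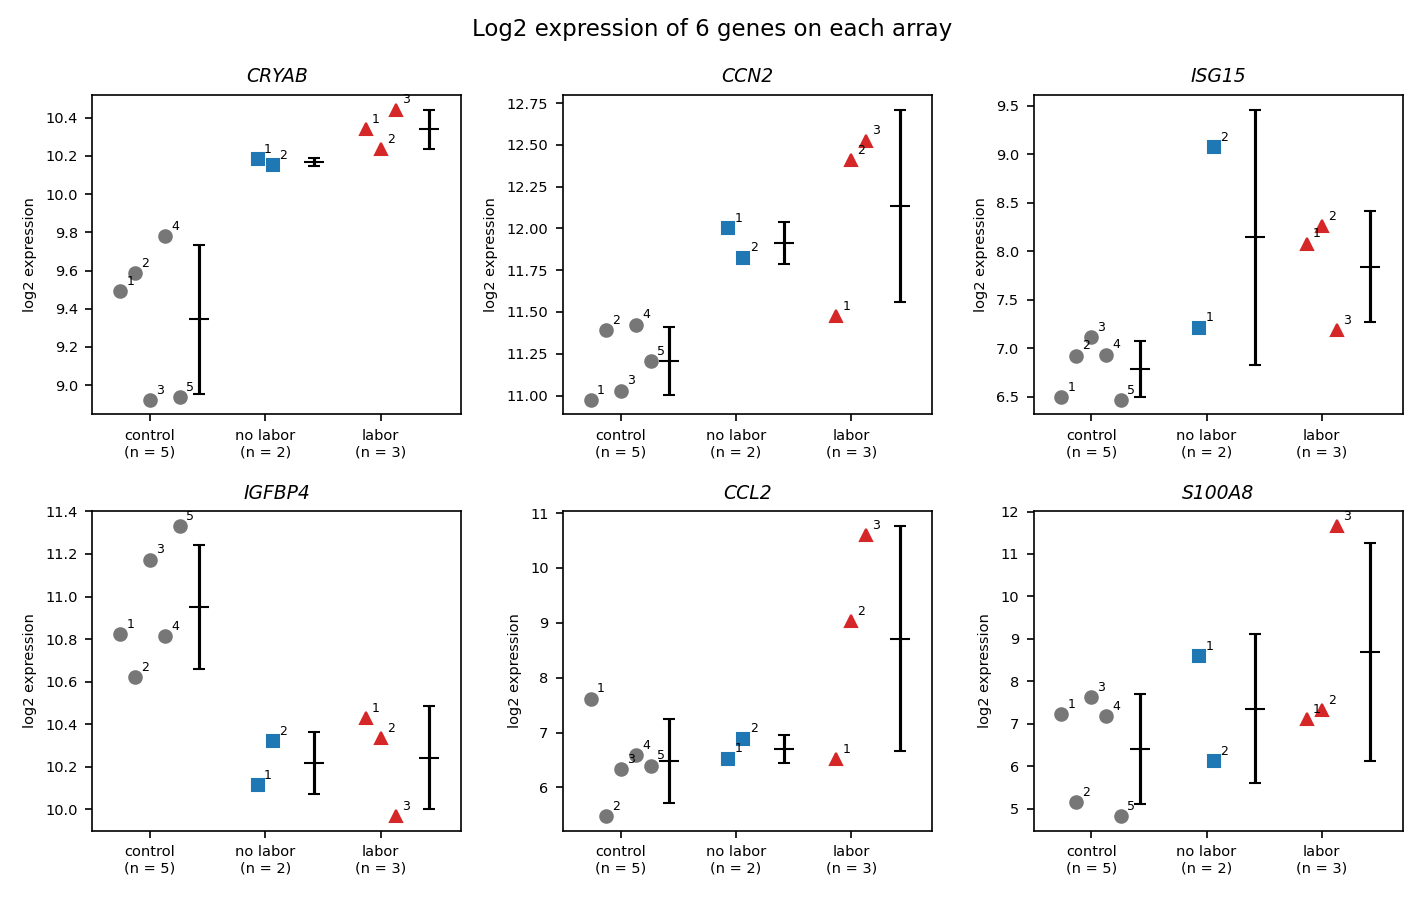
Log2 expression of CRYAB, CCN2, ISG15, IGFBP4, CCL2 and S100A8 on each array, by group; points are animals numbered by replicate, and bars beside them give the mean and SD. CRYAB, CCN2 and ISG15 were higher and IGFBP4 lower in all 5 stretch arrays than in all 5 controls, and S100A8 reached 11.67 in stretch with labor replicate 3.

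Stretch with labor against control compared animals that differed in both balloon stretch and labor, and it cannot tell these apart. Oxidative phosphorylation genes were higher in 22 of 23 members by a mean of 0.20 log2, with list levels of 0.20 ± 0.05 in labor (n = 3) and 0.00 ± 0.07 in control (n = 5). Cell proliferation genes, which serve DNA replication and mitosis, were higher in 21 of 22 members by a mean of 0.59 log2. Type I interferon genes were higher in 18 of 22 by 0.34 log2. camera called these 3 of 37 lists (adjusted p = 8.54e-09, 1.5e-05 and 0.0196). With an estimated correlation the camera adjusted p were 0.533, 0.891 and 0.891, and the exact permutation p of the list levels before adjustment were 0.0179, the smallest that 56 splits allow, 0.161 and 0.179. Of those 56 splits of the 8 arrays, 43 gave 3 or more called lists, and 96.4% of the splits other than the real one called at least 1.

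In the oxidative phosphorylation list, 7 members passed when adjusted over the list alone and 0 over all genes; ATP5F1B differed by 0.43 (SE 0.10), SDHB by 0.34 (SE 0.09), UQCRC1 by 0.27 (SE 0.07) and NDUFA2 by 0.42 (SE 0.12). Among proliferation genes, the cyclins CCNB2 and CCNB1 differed by 1.47 (SE 0.65) and 1.00 (SE 0.49), the replication helicase subunit MCM4 by 0.63 (SE 0.26) and the mitotic kinase AURKA by 0.43 (SE 0.21). Without labor replicate 3 CCNB1 differed by 0.57 and MCM4 by 0.26, and without labor replicate 2 AURKA differed by 0.27. The proliferation level was 1.10 and 0.83 in labor replicates 3 and 2, -0.17 in labor replicate 1, and 0.67 in control replicate 1. On the same 3 arrays with the highest proliferation levels, macrophage markers stood at 0.31 (labor replicate 3), 0.51 (labor replicate 2) and 0.76 (control replicate 1). Without labor replicate 3 the proliferation call was lost (mean 0.33, camera adjusted p = 0.0518), and the interferon call was lost without labor replicate 1, without labor replicate 2 or without control replicate 4 or 5 (means of 0.25, 0.21, 0.33 and 0.26, camera adjusted p = 0.318, 0.33, 0.0532 and 0.0907), and among other settings with the filter at the median level (mean 0.38, camera adjusted p = 0.115). Over all alternatives the camera adjusted p ran from 7.93e-11 to 0.891 for proliferation and from 6.63e-08 to 0.891 for interferon. In the interferon list ISG15 differed by 1.05 (SE 0.39), OAS2 by 0.78 (SE 0.31), RIGI by 0.54 (SE 0.24) and IFIT3 by 0.52 (SE 0.25).

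Genes of the extracellular matrix did not pass as a list (21 of 31 members higher, mean 0.18, camera adjusted p = 0.0753). The collagen cross-linker LOX differed by 0.71 (SE 0.17), fibromodulin FMOD by 0.80 (SE 0.24), tenascin TNC by 0.71 (SE 0.26) and osteoglycin OGN by -1.19 (SE 0.39). Among YAP and stretch responsive genes (17 of 26 higher, mean 0.21, camera adjusted p = 0.1), 3 members passed when adjusted over the list alone; HBEGF differed by 1.34 (SE 0.31), CCN2 by 0.93 (SE 0.22), ITGB1 by 0.48 (SE 0.12) and HSPB8 by 0.42 (SE 0.16). Neutrophil markers were higher in 8 of 9 members (mean 0.69, median 0.31, camera adjusted p = 0.078), with S100A9 at 2.53 (SE 1.14), S100A8 at 2.30 (SE 1.13), MMP8 at 0.31 (SE 0.15) and FPR1 at 0.64 (SE 0.38). The list level was 0.25, 0.11 and 1.71 in labor replicates 1, 2 and 3, and without labor replicate 3 S100A9 differed by 1.15, S100A8 by 0.81, MMP8 by 0.084 and FPR1 by 0.029. CCL2 measured 8.71 ± 2.06 in labor and 6.48 ± 0.76 in control, a difference of 2.23 with a 95% interval of 0.49 to 3.97. Its limma adjusted p was 0.499 over all genes and 0.139 when adjusted over the 8 measured panel genes alone. Without labor replicate 3 CCL2 differed by 1.29. IL6 differed by 0.69 (SE 0.48), IL1B by 0.13, CXCL8 by 0.079, TNF by -0.18, OXTR by 0.20, PGR by -0.34 and ESR1 by 0.024. Chosen after their values were seen, the receptor EPHB1 differed by -2.03 (SE 0.38) and VCAM1 by -1.22 (SE 0.26).

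limma called 0 of 14132 genes (smallest adjusted p = 0.499), with 1321 at an unadjusted p under 0.05, 745 higher and 576 lower. Without labor replicate 1 it called 9 genes, among them HBEGF at 1.80, CCN2 at 1.26 and EPHB1 at -2.58 (limma adjusted p = 0.0267, 0.0395 and 0.0267). Each call rests on a single chosen probe set. In stretch against control the other probe sets of HBEGF and CCN2 did not go higher.

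Stretch without labor against control compared 2 animals with 5. Type I interferon genes were higher in 19 of 22 members by a mean of 0.70 log2, and 9 members passed when adjusted over the list alone (0 over all genes). IFIT1 measured 9.25 ± 0.61 and 7.77 ± 0.32 (difference 1.48, SE 0.33), RIGI differed by 1.14 (SE 0.27), IFIT3 by 1.10 (SE 0.29) and IFIT2 by 0.41 (SE 0.10). Without stretch without labor replicate 2 RIGI differed by 0.54 and IFIT3 by 0.58. Oxidative phosphorylation genes were higher in 15 of 23 members by 0.075 log2, with NDUFS4 at 0.23 (SE 0.08), SDHB at 0.22 (SE 0.10), COX7A1 at 0.32 (SE 0.17) and NDUFA2 at 0.27 (SE 0.14). camera called both lists (adjusted p = 1.74e-11 and 0.0491), and neither with an estimated correlation (camera adjusted p = 0.771 for each with an estimated correlation). The exact permutation p of the list levels before adjustment were 0.0476, the smallest possible with 21 splits, and 0.286. After adjustment over the lists the exact permutation p was 0.93 for each. The interferon levels of the 2 animals were 1.14 and 0.26. Their oxidative phosphorylation levels were 0.073 and 0.078, under the 0.095 of control replicate 4. The oxidative phosphorylation call was lost without any of 6 single arrays: stretch without labor replicate 1 or 2, stretch with labor replicate 2 or 3, and control replicate 2 or 5, with means of 0.051 to 0.078 and camera adjusted p from 0.0511 to 0.0876; the labor arrays do not enter this difference and act on it only through the shared spread. The call was also lost with the filter, quantile normalization, the mean of probe sets or the 3' to 5' covariate (camera adjusted p = 0.198, 0.193, 0.0768 and 0.0731). The list's means there were 0.075, 0.033, 0.071 and 0.086, so of these settings only quantile normalization made the difference much smaller. The list's camera adjusted p ran from 0.00453 to 0.771 over its 17 alternatives.

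Immediate early genes did not pass (13 of 19 higher, mean 0.23, camera adjusted p = 0.0586). The transcription factors KLF2, JUND and KLF6 differed by 0.74 (SE 0.19), 0.26 (SE 0.09) and 0.46 (SE 0.20), and the RNA-binding protein ZFP36 by 0.63 (SE 0.29). Panel genes differed by -0.041 (IL1B), -0.23 (IL6), 0.095 (CXCL8), -0.36 (TNF), 0.22 (CCL2), -0.58 (OXTR), 0.24 (PGR) and 0.24 (ESR1), none past the limma threshold. limma called 0 of 14132 genes (smallest adjusted p = 0.496), with 814 at an unadjusted p under 0.05, of which 47.2% were higher, or 72.4% with arrays centred on their medians.

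Stretch with labor against stretch without labor, 3 animals against 2, asked how labor differed within the stretched animals. Cell proliferation genes were higher with labor in 21 of 22 members by a mean of 0.88 log2, with CCNB2 at 2.39 (SE 0.81), the topoisomerase TOP2A at 2.15 (SE 0.78), ZWINT at 1.48 (SE 0.61) and AURKB at 0.34 (SE 0.13). Type I interferon genes were lower with labor in 20 of 22 members by a mean of -0.36, and 1 member passed when adjusted over the list alone (0 over all genes), with IFIT2 at -0.51 (SE 0.11), IFIT1 at -0.89 (SE 0.36), OASL at -0.32 (SE 0.15) and BST2 at 0.41 (SE 0.19). IFIT1 differed by -0.45 without stretch without labor replicate 2 and OASL by -0.17 without labor replicate 3. Oxidative phosphorylation genes were higher in 20 of 23 members by 0.12 log2, with CYC1 at 0.44 (SE 0.13), NDUFA8 at 0.21 (SE 0.09), UQCRC1 at 0.23 (SE 0.09) and NDUFS3 at 0.22 (SE 0.09). camera called these 3 of 37 lists (adjusted p = 5.37e-07, 0.0014 and 0.0312), and none with an estimated correlation (camera adjusted p = 0.733 for each with an estimated correlation). The exact permutation test cannot go below p = 0.1 with 3 arrays against 2, and gave 0.2, 0.6 and 0.1 before adjustment. The interferon difference turned to 0.084 without stretch without labor replicate 2, and without stretch with labor replicate 3 the only list called was proliferation. The oxidative phosphorylation call was also lost without stretch without labor replicate 1, although the list's mean was then 0.126, no smaller than with all arrays. With the mean of probe sets the list's mean fell to 0.076 and the call was lost (camera adjusted p = 0.331). The list's camera adjusted p ran from 0.0013 to 0.733 over its 17 alternatives.

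Endothelial markers were lower with labor in 9 of 10 members (mean -0.27, camera adjusted p = 0.0528), with EMCN at -0.69 (SE 0.25), TEK at -0.64 (SE 0.26), ERG at -0.44 (SE 0.22) and EGFL7 at -0.35 (SE 0.20). Without stretch without labor replicate 1 ERG differed by -0.12, and without labor replicate 3 EGFL7 differed by -0.13 and TEK by -0.40. Matrix proteases and their inhibitors were higher in 20 of 26 (mean 0.39, camera adjusted p = 0.0914), with ADAMTS4 at 1.05 (SE 0.36), TIMP1 at 0.37 (SE 0.14), ADAMTS1 at 0.54 (SE 0.30) and MMP7 at 0.40 (SE 0.19), or -0.33 with the mean of the MMP7 probe sets. ADAMTS1 differed by 0.083 and TIMP1 by 0.18 without stretch without labor replicate 2, and ADAMTS4 by 0.51 without replicate 1 of that group. Markers of decidual stroma, the lining next to the muscle, were lower in 8 of 9 members (mean -1.09, median -0.32, camera adjusted p = 0.103), and IGFBP1 alone differed by -6.13. IGFBP1, a secreted product of decidual cells, measured 3.75 and 3.81 in labor replicates 2 and 3, 11.43 in labor replicate 1, and 12.36 and 12.55 without labor, and ran from 4.83 to 13.32 in controls. PRL differed by -0.72 (SE 0.45), BMP2 by -0.49 (SE 0.25) and WNT4 by 0.31 (SE 0.16). BMP2 differed by -0.24 without labor replicate 3, WNT4 by 0.12 without stretch without labor replicate 1 and PRL by -0.46 without replicate 2 of that group. Among the panel, CCL2 differed by 2.01 (SE 0.97; 1.07 without labor replicate 3), IL6 by 0.92 (SE 0.60), OXTR by 0.78 (SE 0.52), PGR by -0.58 (SE 0.32), ESR1 by -0.22 (-0.11 without stretch without labor replicate 1), IL1B by 0.17, TNF by 0.18 and CXCL8 by -0.017. Without stretch without labor replicate 2 OXTR differed by 0.13, without replicate 1 of that group IL6 differed by 0.56, and without labor replicate 3 PGR differed by -0.25. Chosen after their values were seen, RASD1 differed by -2.46 (SE 0.39), EPHB1 by -2.33 (SE 0.47), the transcription factor SOX4 by 2.13 (SE 0.44) and VCAM1 by -1.02 (SE 0.32). limma called 0 of 14132 genes (smallest adjusted p = 0.471), with 1261 at an unadjusted p under 0.05, of which 51.3% were higher, or 34.3% with arrays centred on their medians.

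The log2 changes against control of stretch with labor and of stretch without labor correlated across genes at Pearson's 0.205 and Spearman's 0.206. Genes are not independent replicates, and both comparisons share the 5 controls. In 100 simulations of unchanged groups against the same number of controls, Pearson's correlation was 0.324 ± 0.027 (SD over simulations) and Spearman's 0.296. Genes were independent in these simulations too, so this SD leaves out that real genes vary together. With single arrays left out in turn, the observed correlation ran from 0.11 to 0.311. The simulations therefore do not show whether 0.205 lies below the correlation of unchanged groups. The covariance was 0.0118 against 0.0158 simulated. With the controls split 3 against 2 in all 10 ways, the correlation averaged -0.033 and ran from -0.188 to 0.173.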

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

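The tests of RNA degradation, smooth muscle share and a single array were chosen only after the results were seen. So were those of NK cell, macrophage, T and B cell and neutrophil shares, and the splits for genes past the threshold. For covariates and the single array the bound (by 1 SE, more of the difference remains than is lost) was changed. It was then restored with the values known. The comparison of markers with the list replaced an uninformative covariate, also with the values known. For the macrophage share in proliferation this comparison passed its bound narrowly, and the covariate decided nothing.

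For stretch against control, 22 of 100 splits drawn gave at least the 892 genes at an unadjusted p under 0.05 (highest other 1482), and 80 gave at least 3 called lists (highest other 12). For stretch with labor against control, 3 of 56 splits gave at least 1321 genes at an unadjusted p under 0.05 (highest other 2313), and 43 gave at least 3 lists (highest other 10). Chance could not be excluded for these 4 counts. The splits do not test limma's counts of 0 genes, since every split gives at least 0: all 100 for stretch (highest other 5) and all 56 for stretch with labor (highest other 144). The split with 144 genes sets labor replicates 2 and 3 and control replicate 1 against the rest, which points to a structure of the samples that crosses the groups; that split was picked for its count, and the structure was not tested.

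Between the stretched animals with and without labor camera called 3 lists, proliferation 0.88, interferon -0.36 and oxidative phosphorylation 0.12 log2, none of which held with an estimated correlation, and the interferon levels of the 2 groups overlapped. The higher oxidative phosphorylation in stretch was 0.15 log2 before correction. With the 3' to 5' difference as a covariate it was 0.16 (SE 0.056), more than 1 SE above 0.075, the bound set. That argues against RNA degradation as the whole cause. With the smooth muscle markers as a covariate the difference was 0.16 (SE 0.049), also more than 1 SE above the bound. The list's difference exceeded that of the smooth muscle markers (0.080) by only 0.070 (SE 0.12). The marker comparison does not bear out the covariate, so a larger muscle share stays open. The median of the oxidative phosphorylation list, 0.14, lay at percentile 99.99 of 10000 lists matched on level, which argues against a shift that follows intensity. Chance stays open, since 80 of the 100 splits gave as many called lists, as does an effect of stretch, which these tests do not address.

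The interferon difference in stretch was 0.48 log2, and a larger share of a cell type as its whole cause needs markers that rise as much. It exceeded that of NK cell markers (-0.0053) by 0.49 (SE 0.21), which argues against a larger NK cell share, and that of macrophage markers (0.14) by 0.35 (SE 0.36), which leaves macrophages open, as are T and B cells, whose markers (-0.039 and -0.15) fell short by at least 0.52 (SE 0.23) but have levels below the median gene. Neutrophil markers, whose levels also lie below the median gene, rose by 0.54, and the list's difference minus theirs was -0.058 (SE 0.53). With them as a covariate the interferon difference was 0.72 (SE 0.20), more than 1 SE above 0.24, the bound set. The marker comparison does not bear this out, so a larger neutrophil share stays open. With the 3' to 5' difference as a covariate the interferon difference was no smaller, 0.51 (SE 0.28), but within 1 SE of 0.24, so RNA degradation stays open. Chance stays open as for the other lists, as does an effect of stretch, which these tests do not address.

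The proliferation difference between labor and no labor was 0.88 log2. It exceeded that of macrophage markers (0.37) by 0.51 (SE 0.39), more than 1 SE but by a narrow margin. The 3 arrays highest in proliferation are also the 3 highest in these markers. With macrophage markers as a covariate the proliferation difference was 0.63 (SE 0.43), within 1 SE of 0.44, the bound set. The covariate therefore does not bear out the marker comparison, and a larger macrophage share stays open. Without labor replicate 3 the proliferation difference was 0.63 (SE 0.46), also within 1 SE of the bound. Without labor replicate 3 the difference rests on labor replicate 2 (0.83), since labor replicate 1 stood at -0.17. A larger macrophage share, 1 array alone and labor itself stay open with 3 arrays against 2.

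A further 14 values lay far from the others of their group, of 260 sets of 5 values looked at (5.38%), and chance gives about 5%. In stretch these were the highest GCH1 at 7.002, the highest RIGI at 6.32 and the lowest ADAMTS1 at 9.05, all in stretch without labor replicate 2. Stretch with labor replicate 3 had the lowest EXOC2 at 8.24, the highest MMP8 at 3.50 and the lowest EGFL7 at 6.85. Control replicate 1 had the highest RNF167 at 9.29, the lowest KCNMA1 at 7.11, the lowest ITGA8 at 8.54 and the lowest UQCRC1 at 9.83. The other controls had the highest KGD4 at 8.26 (replicate 4), the highest OPA1 at 7.93 and TAP1 at 7.52 (both replicate 5) and the highest PRL at 4.80 (replicate 2).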

How the results depend on the processing

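Leaving out the 2 arrays that stood furthest apart (stretch with labor replicate 3 and control replicate 1), the 3' to 5' covariate and the exact test of list means were added after seeing the data. limma's count of 0 genes held in all 4 comparisons under each other prior, weighting, normalization, probe-set rule, filter and model and at an adjusted p under 0.1. At an unadjusted p under 0.05 with at least a 1.5-fold change the counts were 72 for stretch, 208 for stretch with labor, 103 for stretch without labor and 309 between the stretch groups. Leaving out 1 array gave 0 to 9 genes for stretch with labor, 0 to 1 for stretch without labor and 0 to 1 between the stretch groups; the 9 came without labor replicate 1, and the single genes without stretch without labor replicate 1 or, between the stretch groups, also without labor replicate 1. Where this leaves 1 array in an arm, that array is assumed to vary like the others. The signal over background was not analysed here, since scanner files were not used.

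List counts (3, 3, 2 and 3 in the order above) depended on the setting. With an estimated correlation and with the exact permutation test of list means they were 0 in each comparison. Quantile normalization gave 6 for stretch and 5 for stretch without labor, the filter, under which 21 lists were tested and proliferation was not among them, 1 for stretch with labor and 5 between the stretch groups, and the mean of probe sets 1 for stretch without labor. Without the 2 arrays that stood apart 5 lists passed in each comparison against control, and with the 3' to 5' covariate 5 for stretch and 1 for stretch without labor. Leaving out 1 array gave 4 to 6, 2 to 6, 1 to 7 and 1 to 8 lists. The interferon difference between the stretch groups ran from -0.80 to 0.084. The cause was not tested.

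The replicate numbers were not taken as pairs: of 7 same-numbered pairs, 2 had a correlation of deviations over 0.1 (-0.088 to 0.212). The check holds no pairs of different numbers, so it cannot exclude a pairing or a shared batch. As a replicate block the numbers gave 7, 6, 9 and 5 lists and 0 genes in each comparison. Antigen presentation in stretch (0.049, camera adjusted p = 0.378) and interferon in stretch with labor (0.22, camera adjusted p = 0.168) were not called under the block. There OXTR (0.32) and TBXAS1 (-0.024) reversed in stretch, ESR1 (-0.043) in stretch with labor, and IL1B (0.0026), IL6 (0.21) and PGR (-0.097) in stretch without labor.

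Of 161 gene values none had passed, and 17 reversed under some setting other than leaving out 1 array; the cause was not tested. With the mean of probe sets DDX60 (0.079) and NOS3 (-0.073) reversed in stretch, IL1B (0.24) and IL6 (0.048) in stretch without labor and MMP7 (-0.33) between the stretch groups. With array weights PGR (0.040) reversed in stretch, IL1B (-0.049) and CXCL8 (-0.041) in stretch with labor and IL1B (-0.022) between the stretch groups. Without the 2 arrays that stood apart IL1B (-0.037), IL6 (-0.056) and PGR (0.19) reversed in stretch, IL1B (-0.083), CXCL8 (-0.043) and PGR (0.066) in stretch with labor, IL1B (0.0083) in stretch without labor and IL1B (-0.091) between the stretch groups. With the 3' to 5' covariate IL1B (-0.065), IL6 (-0.058), OXTR (0.28) and KCNMA1 (-0.036) reversed in stretch and ESR1 (-0.015) in stretch with labor.

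Leaving out 1 array moved values across 0 in these ranges. In stretch these were CXCL8 (-0.0036 to 0.18), IL1B (-0.086 to 0.16), OXTR (-0.36 to 0.16) and PGR (-0.24 to 0.11). In stretch with labor they were CXCL8 (-0.10 to 0.26), ESR1 (-0.045 to 0.11), IL1B (-0.13 to 0.37) and OXTR (-0.13 to 0.46). In stretch without labor they were CCL2 (-0.028 to 0.51), IL1B (-0.15 to 0.071), IL6 (-0.59 to 0.13) and OXTR (-1.22 to 0.061). Between the stretch groups they were CXCL8 (-0.20 to 0.17), IL1B (-0.091 to 0.41) and TNF (-0.035 to 0.39). Without crossing 0, a further 20, 13, 7 and 18 gene values in the order above moved by over 1.5 times when 1 array was left out, 9, 10, 0 and 9 of them without labor replicate 3. Beside those given with the results, the value that moved most was, in stretch, IL6 (0.066), GADD45B (0.38) and ITGA8 (-0.65) without labor replicate 3, TNFAIP2 (-0.25) without labor replicate 2, KCNMA1 (0.052) without labor replicate 1, ESR1 (0.052), CSF3R (0.080) and NOS3 (0.063) without stretch without labor replicate 1, CLDN4 (-0.14), PPP1R14A (0.18), TAGLN (0.062) and PTGES3 (-0.15) without control replicate 1, CTSS (0.20), SOD2 (0.15) and TBXAS1 (0.031) without control replicate 4 and KRT8 (0.11) without control replicate 5. In stretch with labor it was IL6 (0.36), PGR (-0.014) and SOX4 (0.55) without labor replicate 3, TNF (-0.060) without labor replicate 2 and CCNB2 (2.26) without labor replicate 1. In stretch without labor it was CXCL8 (0.041), PGR (0.056) and ESR1 (0.13) without replicate 1 of that group and TNF (-0.15) and ZFP36 (0.41) without replicate 2, and between the stretch groups AURKB (0.19) and UQCRC1 (0.14) without stretch without labor replicate 1. HBEGF (1.80), CCN2 (1.26) and EPHB1 (-2.58) passed in stretch with labor without labor replicate 1. The correlation of the 2 changes was 0.162 in genes at or above the median level, -0.033 with split controls and 0.11 to 0.311 with 1 array left out.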

Other observations

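The list level of decidual stroma markers ran from -0.73 to 0.86 in controls and from -1.48 to 0.49 in stretch, and IGFBP1 spanned 3.75 to 13.32 log2 over the 10 arrays. Epithelial markers were lower than the control mean in all 5 stretch arrays (-0.47 to -0.20), while controls ran from -0.29 to 0.47. Adipocyte markers were lowest in labor replicate 3 (-0.95) and labor replicate 2 (-0.64). Mesothelial markers stood at 0.83 in labor replicate 2, and platelet markers at 0.77 in stretch without labor replicate 1, whose neutrophil level was 0.72.

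Other lists did not pass camera in stretch against control. Hypoxia and glycolysis genes had a mean of -0.0018 and a median of 0.055 (camera direction higher, adjusted p = 0.614). Genes of the unfolded protein and heat shock response had a mean of 0.024 and a median of -0.022 (camera adjusted p = 0.899), and those of calcium and potassium handling a mean of -0.057 (camera adjusted p = 0.899). Glucocorticoid and progestogen responsive genes had a mean of -0.045 and a median of 0.046 (camera direction higher, adjusted p = 0.762). Smooth muscle cell markers had a mean of 0.080 (camera adjusted p = 0.338), and macrophage markers a mean of 0.14 and a median of -0.012 (camera adjusted p = 0.626).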
